A study of Mus musculus with 4 samples.

How the data were processed

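The data are 5′ single-cell RNA sequencing libraries (10x Genomics) of CD45+ cells sorted from crypts of the mouse small intestine. There were 2 samples from mice on a control diet and 2 from mice on a diet rich in cystine, the oxidised dimer of cysteine, with 18000 cells loaded per sample. Groups were taken from the sample titles, because the treatment field of the labels reads "Control" for all 4 samples. The labels do not say whether each sample is 1 mouse or a pool, nor whether the samples come from separate animals, so p-values measure only the spread between these 4 samples. The description of the series speaks of matched control samples, without saying how they were matched or whether replicate numbers mark pairs. No pairing was assumed, and the replicate number was used as a block in an alternative, which changed the number of genes called.

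The deposited matrices hold UMI counts per gene and cell barcode, unnormalised, for barcodes called by the authors, each with at least 500 UMIs, over the same 32285 genes in all samples. The deposited gene and barcode lists hold names only. The submitters' notes name Cell Ranger 3.1.0, Seurat 4.0.1 and genome build GRCm39, whereas the matrix headers name software version 7.0.1. The annotation at hand is for another build, so no coordinates are given; genes are named by the symbols in the files. Per-sample totals were 27229695 and 30684435 UMIs in control replicates 1 and 2 and 31301936 and 31215609 in cystine replicates 1 and 2, over 16865, 15391, 19351 and 16653 barcodes. Cystine replicate 1 thus has more barcodes than cells loaded.

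Barcodes with at least 300 genes and at most 10% mitochondrial UMIs were kept, and the barcodes with the highest Scrublet scores were removed as doublets at a rate of 0.8% per 1000 barcodes in each sample. That left 58725 of 68260 barcodes. Counts were scaled per cell and log-transformed; 2000 variable genes, without immunoglobulin, T cell receptor and mitochondrial genes and Il22, gave 30 principal components and a graph of 15 neighbours, which the Leiden algorithm divided into 25 clusters at resolution 1. Secretory genes of epithelial cells were left out of the clustering genes after the data had been seen. Clusters were named with the suffix "-like" from 27 marker lists: at least 3 markers detected in at least 10% of the cluster's cells, a mean log2 enrichment of at least 1, and at least 1 marker among the 10 leading genes. T cell clusters with Cd3e in at least 50% of cells, markers of γδ and of natural CD8αα cells, and Cd8b1 in less than 10% of cells formed the class "γδ or natural CD8αα T-like". A cluster with Cd3e in at least 50% of cells and the markers of a non-T type was left unnamed. This gave 9 named classes and 6 unnamed clusters, which held 3.19% and 2.13% of cells in the controls and 4.22% and 3.74% in the cystine samples.

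Class shares were compared with the edgeR quasi-likelihood test on cell numbers per sample, with the kept cells as library size. UMIs were summed per sample over all kept cells and over each of the 6 classes with at least 30 cells in every sample, and each set of sums was fitted with edgeR (filterByExpr, TMM, glmQLFit, glmQLFTest). P-values were adjusted by Benjamini-Hochberg within each class, and the threshold was an adjusted p of 0.05. The difference of the diet effect between CD8αβ T-like and CD4 T-like cells was tested as an interaction with the sample as a block. The 24 gene lists covered T cell programmes, metabolism, stress and the marker genes of other cell types, and were tested with limma camera at a preset correlation of 0.01 where at least 3 members were measured, with fry and camera with an estimated correlation beside it. Values are TMM-scaled CPM, counts brought to a common total, as mean ± SD over 2 samples, and log2 fold changes are cystine over control with standard error (SE). Shares of cells carry exact Clopper-Pearson intervals at 95%, and a count of 0 is given the limit of 3 counts; both cover counting error only. Shares of cells with an Il22 UMI were compared by a two-sided exact permutation test, which with these 4 samples cannot give a p below 0.333, also after thinning each cell to 1000 UMIs.

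Genes were named by a rule fixed before the data were examined, as were the markers, gene lists and tests. The rule took genes past the threshold whose cystine samples both lay above or both below the controls, with a group mean of at least 20 CPM: up to 12 rises and 12 falls in all kept cells and in CD8αβ T-like cells, 4 and 4 in other classes, plus up to 4 members of each gene list that passed and 17 genes chosen in advance, with receptor genes given as counts. Of the genes that met the rule, 2 are not reported here. The alternatives chosen before the data were examined were DESeq2 size factors, a DESeq2 Wald test, no low count filter, a replicate block, omission of immunoglobulin and T cell receptor genes, a cell filter of at least 800 genes and at most 5% mitochondrial UMIs, no doublet removal, other cluster resolutions, other denominators, TMM on cell counts, CD8αβ T cells defined by UMIs per cell, and omission of each sample in turn. After the data had been seen, fits without the barcode with the most Il22 UMIs, without secretory genes of epithelial cells, with those genes among the clustering genes, and with genes changed in any class, or in CD8αβ T-like cells, left out of the clustering genes were added.

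Data were simulated at the same depth, with a common spread for all genes and no correlation between genes. For the gene tests only genes of at least median expression were changed. On these data the edgeR test found 50 of 67 genes changed by 1 on the log2 scale in CD8αβ T-like cells and 26 of 67 in all kept cells, with 2 and 1 false calls. The interaction test found 29 of 67, with 10 false calls, and false calls numbered 8 in monocyte-like cells and 2 or 3 in the other classes. A simulated 4-fold change in a class share, that of CD8αβ T-like cells, was called in 11.5% of 200 draws. The draws gave every class 1 common spread, estimated over all 15 classes and unnamed clusters. The rate therefore need not hold for a class with a spread of its own. A list raised by 0.5 on the log2 scale was found by camera at the preset correlation in every class, with 0 other lists called, but by the estimated correlation in none, with adjusted p from 0.0843 to 0.408. With uncorrelated genes, this could not show the false calls that lists of correlated genes may give. Tools were Python 3.11.15, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.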

Results

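CD45+ cells, which are blood-derived immune cells, were sorted from small-intestinal crypts of mice on a control diet (2 samples) or a cystine-rich diet (2 samples), and their messenger RNA was counted per cell. After filtering, 14558 and 13481 cells remained in control replicates 1 and 2, with a median of 1335 and 1713 UMIs per cell. The cystine replicates 1 and 2 kept 16317 and 14369 cells, with medians of 1294 and 1487 UMIs. The summed UMIs of kept cells lay between 22367265 and 25742401 per sample. The comparison of the diets asks, by the title of the series, whether dietary cysteine changes CD8 T cells and their IL-22, the cytokine that acts on the gut epithelium.

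At the resolution used, most cells in every sample were γδ or natural CD8αα T-like cells, the resident T cells of the gut epithelium. They made up 87.8% ± 2.0 of kept cells on the control diet and 68.6% ± 6.33 on the cystine diet (SD, n = 2 each). At resolution 0.5 the class held 47.6% and 66.9% of control and 35.6% and 34.2% of cystine cells, while 1 cluster of 23.4% to 40.5% of cells was left unnamed. CD8αβ T-like cells, the conventional killer T cells, made up 2.25% ± 0.20 and 9.15% ± 0.12 (n = 2 each), a ratio of 4.07. Plasmacytoid dendritic-like cells, the main producers of type I interferon, made up 1.95% ± 0.27 and 3.99% ± 0.46. B-like cells made up 2.49% ± 0.25 of control cells, against 15.3% of cystine replicate 1 (95% interval 14.8% to 15.9%) and 6.33% of cystine replicate 2 (5.93% to 6.74%). CD4 T-like cells stood at 1.65% ± 0.49 and 1.85% ± 0.35, monocyte-like cells at 0.687% ± 0.0777 and 0.442% ± 0.0535, and plasma cell-like cells at 0.207% ± 0.00895 and 0.628% ± 0.386. Type 2 dendritic-like cells stood at 0.254% ± 0.107 and 0.400% ± 0.0839, and mast-like cells at 0.10% ± 0.00543 and 0.108% ± 0.0927.

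By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of the 15 classes and unnamed clusters passed. At an unadjusted p below 0.05 there were 3, the CD8αβ T-like, B-like and plasmacytoid dendritic-like cells. The log2 fold change of the CD8αβ T-like share was 2.02 (SE 0.32, adjusted p = 0.0656), that of the B-like share 2.12 (SE 0.58, adjusted p = 0.197), and that of the plasmacytoid dendritic-like share 1.04 (SE 0.33, adjusted p = 0.204). The CD8αβ T-like share passed with TMM on the cell numbers (2.37, adjusted p = 0.0235), with T cells alone as the denominator (2.23, adjusted p = 0.00223) and without B-like and plasma cell-like cells (2.17, adjusted p = 0.0240). With T cells alone as the denominator the γδ or natural share fell (-0.15, adjusted p = 0.0172), whereas over all kept cells it was at -0.35 (SE 0.31, adjusted p = 0.597), and over all alternatives its adjusted p lay between 0.0172 and 0.922. The shares of the 3 T cell classes add up to the whole, so this fall is not separate from the CD8αβ T-like rise. Over all alternatives the log2 fold change of the CD8αβ T-like share lay between 1.23 and 2.37. With all 4 samples its adjusted p lay between 0.00223 and 0.181. The lowest value came from cells with UMIs of Cd8a, Cd8b1 and Cd3 and none of Trdc or Cd4, which were 3.65% ± 0.220 of control cells and 8.57% ± 0.649 of cystine cells. Gzmk, which changed with the diet, is among the leading genes of the CD8αβ cluster. Clustering without the 186 genes changed in any class gave no cluster named CD8αβ, and 2257 of the 3442 CD8αβ T-like cells joined a cluster of 3413 cells named CD4 T-like. That cluster had Cd8b1 among its leading genes and detected Cd8b1 in 58.4%, Cd8a in 66.9% and Cd4 in 8.73% of cells. The log2 fold change of its share was 1.24 by the edgeR test (adjusted p = 0.112). Clustering without the 95 genes changed in CD8αβ T-like cells gave CD8αβ T-like shares of 3.02% ± 0.295 and 9.53% ± 0.146. In cells thinned to 1000 UMIs and chosen by the same UMIs, the shares were 3.46% and 2.79% in the controls and 7.25% and 7.87% in the cystine samples, with cells of fewer UMIs left out.

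**Figure D1:**
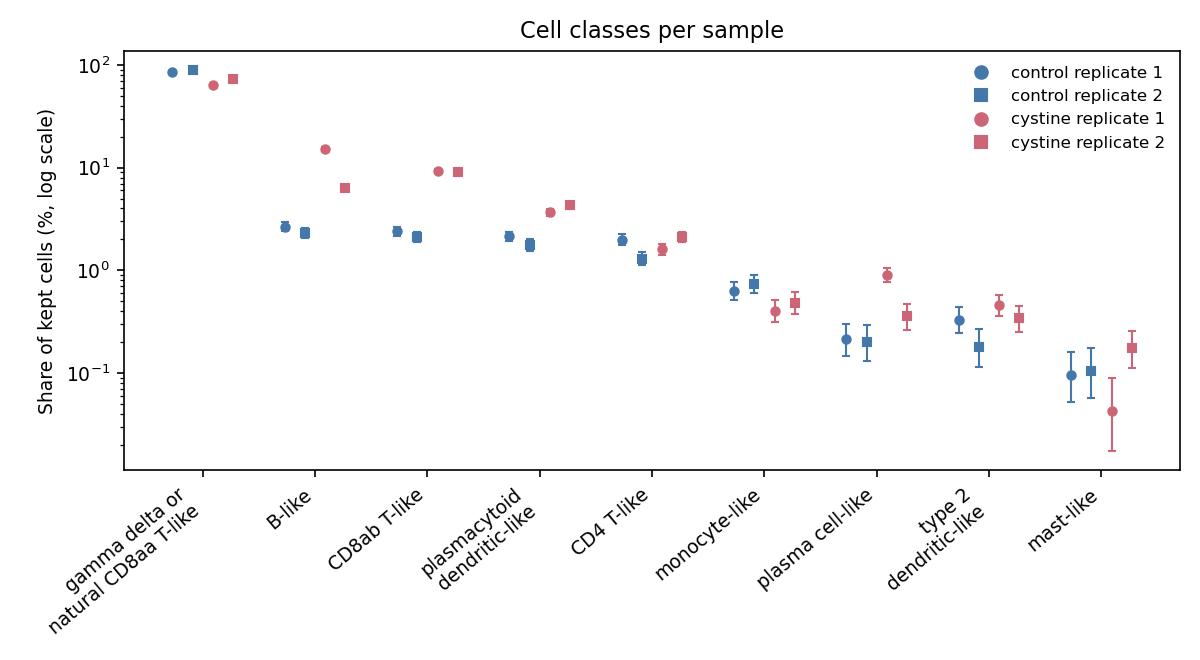
Share of kept cells, in percent, in each named class for the 2 control and 2 cystine samples; bars are 95% Clopper-Pearson intervals of each sample. The CD8αβ T-like share is 2.39% and 2.11% in the controls and 9.24% and 9.07% in the cystine samples.

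Within CD8αβ T-like cells, 24 genes rose and 71 fell of 8160 tested. The cystine samples had more RNA of the granzyme gene Gzmk (ENSMUSG00000042385), a serine protease of killer cell granules, which went from 292 ± 30.7 to 1095 ± 100 CPM (log2 fold change 1.91, SE 0.12, adjusted p = 4.21e-08). Ly6a, a surface protein of activated T cells, rose from 109 ± 53.9 to 412 ± 56.1 CPM (1.93, adjusted p = 4.19e-05). The chemokine genes Ccl4 and Ccl5 rose by 1.19 and 0.47 (adjusted p = 0.000663 and 0.0048). Cd7, a surface protein of T cells, fell from 2815 ± 11.8 to 1084 ± 317 CPM (-1.38, adjusted p = 2.13e-05). Tcf7, a transcription factor of naive and memory T cells, fell from 162 ± 32.8 to 68.4 ± 7.37 CPM (-1.24, adjusted p = 0.000796). Cd40lg, a helper signal for B cells, fell by 2.69 on the log2 scale, Nsg2 by 2.54, Ddc by 1.70, Capn3 by 1.63 and Trat1, which binds the T cell receptor, by 1.33. The other named rises were Ifitm10 at 2.49, Zmym2 at 2.13 and the histone deacetylase gene Hdac7 at 1.22, and the other named falls Zg16 at -2.78, Gna15 at -2.20, Abcb9 at -1.89, Tbc1d4 at -1.53 and the kinase gene Pim2 at -1.25.

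Of 13 γδ receptor genes measured in this class 7 fell and 0 rose, with a median log2 fold change of -1.29, and of 47 αβ receptor genes 2 rose and 6 fell; the difference between these groups was not tested. Gzmk, which rose in CD8αβ T-like cells, is a leading gene of their cluster and of a γδ or natural CD8αα T-like cluster. In γδ or natural CD8αα T-like cells its log2 fold change lay between -1.65 and -0.69 when 1 sample was left out. Of the falls named above in CD8αβ T-like cells, Tcf7, Capn3 and Nsg2 are leading genes of γδ or natural CD8αα T-like clusters, as is Cd7 at resolution 0.5. Genes of epithelial secretory cells were also among the changed genes, 7 rises and 1 fall. Defa24, a defensin of Paneth cells, had 0 UMIs in both controls, which allows up to 5.57 and 5.77 CPM, and 405 ± 188 CPM in the cystine samples. AY761184, Lyz1 and Defa22 likewise had 0 UMIs in the controls, and Defa30 had 3 UMIs there in all. Ly6a, Gzmk, Nsg2, Ddc, Capn3, Cd7, Trat1 and Tcf7 passed under each alternative tried except the fit without a low count filter, in which 0 genes passed. In cells chosen by their UMIs, 64 genes passed and 36 of them were among the 95. Ccl4 (0.10), Ccl5 (0.04), Ifitm10 (1.11), Zmym2 (0.33), Hdac7 (0.95), Cd40lg (-1.65), Gna15 (-0.36), Abcb9 (-0.98), Tbc1d4 (-1.15) and Pim2 (-0.82) did not pass there, with adjusted p from 0.0641 to 0.933. Without control replicate 1 there were 223 genes, 81 of them shared with the 95, and without cystine replicate 2 there were 169, with 76 shared. The DESeq2 Wald test called 33, of which 32 were shared. Cd40lg and Abcb9 were not called without control replicate 2, Ifitm10 and Tbc1d4 without control replicate 1, Ifitm10, Zmym2, Pim2, Zg16, Gna15 and Tbc1d4 without cystine replicate 1, or Zg16, Gna15 and Tbc1d4 without cystine replicate 2.

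**Figure D2:**
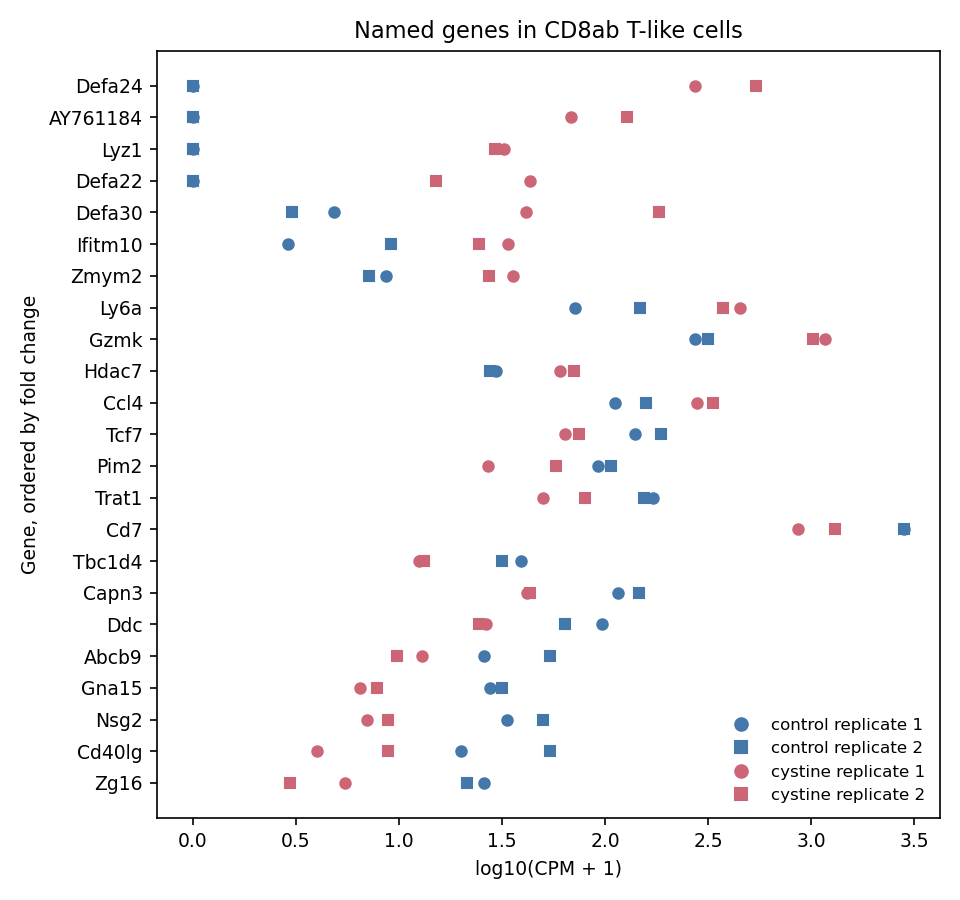
Expression of genes named in CD8αβ T-like cells, as log10 of CPM + 1, in each of the 2 control and 2 cystine samples. Gzmk and Ly6a lie higher in both cystine samples, and Cd7, Tcf7 and Nsg2 lie lower.

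Of the 21 gene lists tested in CD8αβ T-like cells 5 passed camera at the preset correlation. Cytotoxic effectors rose as a list (adjusted p = 1.36e-05): of 18 measured members Gzmk, Ccl4 and Ccl5 rose, 0 fell and 15 did not pass, and 6 rose when adjusted over the list alone. No list was tested in cells chosen by their UMIs, so whether this rise depends on how the class was defined is not known. There Gzmk rose by 1.94, while Ccl4 (0.10), Ccl5 (0.04) and Gzmb (-0.82) did not pass. Gzma and Gzmb, the main granzymes, had log2 fold changes of 0.34 (SE 0.13) and -0.23 (SE 0.22) and did not pass. Gzma passed in 4 of 14 alternatives (0.31 with the block, 0.30 without control replicate 1, 0.38 without control replicate 2 and 0.62 without cystine replicate 1), was 0.0399 without cystine replicate 2, and was -0.50 without passing in cells chosen by their UMIs. Gzmb passed in 3 of 14 (-0.33 with the block, -0.34 without control replicate 1 and -0.91 without cystine replicate 2) and was 0.26 without cystine replicate 1, where it did not pass. Over these alternatives the adjusted p ran from 1.24e-07 for Gzma and 1.88e-11 for Gzmb to 0.99999 for both. Cytosolic ribosomal protein genes fell as a list (adjusted p = 3.86e-23), with 23 of 23 members below 0 and a median of -0.28. Of these Rpl32, Rplp1 and Rpl13 fell (none of them without cystine replicate 1, and Rpl32 alone without cystine replicate 2, and none in cells chosen by their UMIs, with adjusted p from 0.124 to 0.241) and 20 did not pass, and 18 fell when adjusted over the list alone. Oxidative phosphorylation genes fell as a list (adjusted p = 0.00995; median -0.12), with 0 of 24 members called and 2 falls when adjusted over the list alone. The list of type 17 and type 22 cytokines and regulators fell (adjusted p = 0.0157), of whose 6 members Tmem176b fell (-3.87, from 8 UMIs in each control to 2 in each cystine sample), 5 did not pass, and 2 fell when adjusted over the list alone. Enterocyte genes, marking another cell type, rose as a list (adjusted p = 0.000204), with 0 of 6 members called and 4 rises when adjusted over the list alone. All 5 lists had an adjusted p = 0.489 with an estimated correlation, and from 0.210 to 0.430 with fry.

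The diet effect differed between CD8αβ T-like and CD4 T-like cells for 24 of 6672 genes by the interaction test, 5 with a higher and 19 with a lower effect in CD8αβ T-like cells. Ly6a had log2 fold changes of 1.93 and -0.10 in these classes, a difference of 2.07 (SE 0.28, adjusted p = 0.00088). Cxcr6, a homing receptor of tissue T cells, differed by 1.78 (adjusted p = 0.0197). Without control replicate 1 or 2, or cystine replicate 1 or 2, between 30 and 120 genes differed.

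Il22 (ENSMUSG00000074695), the gene of IL-22, was found in 35 kept cells. Of these 26 were CD4 T-like, 7 were γδ or natural CD8αα T-like and 0 were CD8αβ T-like. By their own UMIs 11 of the 35 had Cd4, 13 had Cd8a and 2, both in cystine replicate 2, had Cd8b1, and 0 were CD8αβ cells as defined by UMIs. In the CD4 T-like cluster as a whole Cd4 was detected in 25.2% of cells, Cd8a in 26.5%, Cd8b1 in 16.7% and Trdc in 10.0%. The name of the class thus does not make each of its cells a CD4 T cell. The 348 and 284 CD8αβ T-like cells of the controls held 0 cells with an Il22 UMI, which allows up to 0.862% and 1.06% of cells with such a UMI. The 1507 and 1303 cells of the cystine samples also held 0, which allows up to 0.199% and 0.230%. These limits do not cover cells that express Il22 without a UMI being captured. Among CD4 T-like cells 4.07% ± 0.0975 had an Il22 UMI on the control diet and 1.24% ± 0.127 on the cystine diet (n = 2 each, exact permutation p = 0.333, the smallest these samples allow). After thinning to 1000 UMIs the shares were 2.65% ± 0.384 and 1.35% ± 0.209. B-like cells, which should lack the gene, held 0 cells with an Il22 UMI of 388, 311, 2500 and 909, at median depths of 1102.5, 1258, 1130 and 1279 UMIs against 1616, 1700, 1406 and 1560 in CD4 T-like cells.

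The Il22 UMIs numbered 20 and 8 in the controls and 4 and 341 in cystine replicates 1 and 2. A single barcode of cystine replicate 2 held 333 of them, 10.9% of its 3060 UMIs, and the next highest cell held 4. This barcode fell in the CD4 T-like cluster and had UMIs of Cd3e (1), Cd3g (2), Trac (1) and Icos (5) but 0 of Cd4, Cd8a, Cd8b1, Trbc1 and Trbc2. It also had UMIs of Ccl5 (18), Gzma (16) and Tmem176b (6), and more UMIs in all than 93.0% of its class in that sample, whose median was 1560. The fitted log2 fold change of Il22 was 3.46 (SE 1.55, adjusted p = 0.570) in all kept cells and 3.83 (SE 1.14, adjusted p = 0.552) in CD4 T-like cells. Without that barcode it was -1.34 and -1.14, and without cystine replicate 2 -1.87 and -1.35. Without cystine replicate 1 it passed in both (4.42, adjusted p = 1.90e-36, and 4.80, adjusted p = 0.000359). In CD4 T-like cells it also passed without control replicate 1 (3.82, adjusted p = 7.33e-16), without a low count filter (3.84, adjusted p = 1.23e-33) and with the block (3.12, adjusted p = 1.04e-20). Over all alternatives the adjusted p reached 0.847 in all kept cells and 0.9997 in CD4 T-like cells. In CD4 T-like cells without the barcode, Il22 stood at 23.2 ± 0.653 CPM, unscaled, on the control diet and 10.2 ± 1.66 on the cystine diet. Il17a, the gene of a cytokine often made beside IL-22, had log2 fold changes of -2.06 (SE 0.61, adjusted p = 0.552) in CD4 T-like and -2.27 (SE 1.13, adjusted p = 0.630) in all kept cells. It lay between -6.26 and -1.18 and between -6.58 and -1.01 when 1 sample was left out. It passed in 5 of 13 alternatives in CD4 T-like cells (without a low count filter, with the block, and without control replicate 1, control replicate 2 or cystine replicate 2) and in 2 of 13 in all kept cells (without cystine replicate 1 or 2), with adjusted p over all alternatives from 2.33e-21 to 0.9997 and from 1.46e-17 to 0.9999.

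**Figure D3:**
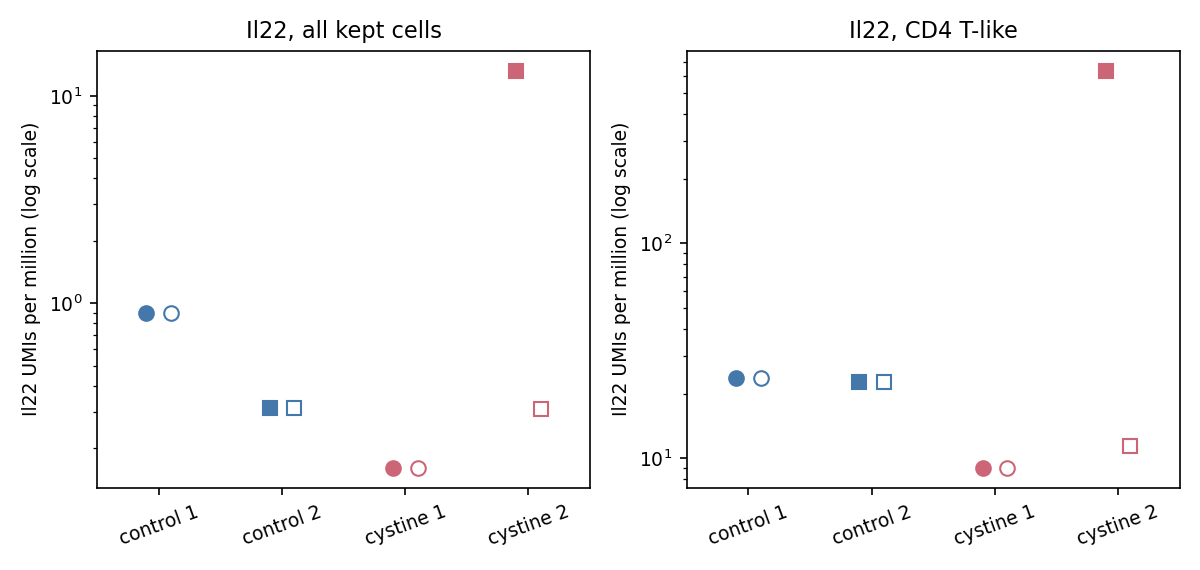
Il22 UMIs in CPM (unscaled counts), on a log scale, in all kept cells and in CD4 T-like cells of each sample, with all cells (filled) and without the barcode with the most Il22 UMIs (open). Cystine replicate 2 is the highest sample with that barcode and not without it.

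Over all kept cells 21 genes rose and 0 fell of 14076 tested. They were 8 immunoglobulin variable genes, 8 genes of epithelial secretory cells and 5 others. The secretory genes included the Paneth cell genes Lyz1, at 1.87 ± 0.620 CPM on the control and 51.0 ± 19.0 CPM on the cystine diet (log2 fold change 4.76, SE 0.36, adjusted p = 0.0166), Defa22 (6.82), Defa21 (6.92) and AY761184 (6.92). Defa17 had 0 UMIs in the controls and 95 and 120 in the cystine samples. The named others were Ly6a (1.48, adjusted p = 0.0304), Ly6d (1.45), B3gnt8 (1.33) and Pld4 (1.01), of which Pld4 is a leading gene of the plasmacytoid dendritic-like cluster. Averaged over classes with equal weight, the changes of these 4 were 0.41, 0.54, 0.27 and 0.42. Of the 17 genes chosen in advance 0 passed, with adjusted p from 0.151 to 0.977. At an unadjusted p below 0.05 there were 1337 genes. The DESeq2 Wald test called 367 genes, 299 up and 68 down. The count was 1 without control replicate 1, 0 without control replicate 2, 542 without cystine replicate 1 and 895 without cystine replicate 2.

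In all kept cells 8 of 24 lists passed camera. Genes of MHC class II presentation rose as a list (median 1.48, adjusted p = 3.46e-15), with 0 of 12 members called and 12 rises when adjusted over the list alone. Its named members H2-Aa (1.56), Ifi30 (1.18), Ctss (0.64) and H2-DMb1 (0.63) averaged 0.44, 0.03, -0.13 and -0.46 over classes of equal weight. Immunoglobulin constant genes rose as a list (median 1.80, adjusted p = 1.19e-08; 0 of 11 called, 9 over the list alone), and the B-like share was higher in both cystine samples. The list of naive and circulating T cells rose (median 0.62, adjusted p = 1.81e-05; 0 of 16 called, 4 over the list alone), and cytotoxic effectors fell (median -0.34, adjusted p = 2.05e-08; 0 of 22 called, 2 over the list alone). Paneth and goblet cell genes rose as a list (adjusted p = 5.03e-06) with 5 of 18 members called, 10 rises and 1 fall over the list alone. Genes of tissue residency and gut homing (adjusted p = 0.00926) and of inhibitory receptors (adjusted p = 0.0217) fell, with medians of -0.19 and -0.24, and genes of stroma, endothelium and red cells rose (median 1.42, adjusted p = 0.00415); 0 members of these 3 lists were called, over all genes or when adjusted over the list alone. With an estimated correlation each of the 8 had an adjusted p from 0.547 to 0.573.

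In γδ or natural CD8αα T-like cells 23 genes rose and 4 fell of 12412, and 18 of the rises were genes of epithelial secretory cells. Lyz1 went from 0.174 ± 0.170 to 36.4 ± 9.05 CPM (log2 fold change 7.61, adjusted p = 9.68e-06), Defa24 from 3.35 ± 2.69 to 422 ± 227 CPM (6.95), and Ang4, Defa21, Defa22 and Defa30 rose by 6.60, 6.80, 6.35 and 7.04. Rbp2, an enterocyte gene, rose by 1.71, and Zg16, a gene of goblet cells, fell by 1.74. The make-up of this class differed between samples: a cluster led by Gzmk, Scin and Trdv5 held 13.4% and 21.6% of its cells in the controls and 6.14% and 7.41% in the cystine samples. Of 24 lists 12 passed. MHC class II (adjusted p = 0.000152), immunoglobulin constant (1.08e-06), enterocyte (3.37e-07), Paneth and goblet cell (2.75e-16), epithelial IL-22 target (0.0146) and stroma (0.0347) genes rose as lists. These lists hold genes of other cell types: Cd74, H2-Aa and H2-DMb2 of MHC class II lead the B-like cluster. The B-like share was higher in both cystine samples. Whether these rises come from the T cells themselves was not tested. Of the IL-22 targets, which are genes of another cell type, Reg3g and Reg3b were at -0.66 without cystine replicate 2. Reg1 and Pigr stayed above 0 whichever sample was left out. Cytotoxic effectors (1.04e-05), T cell receptor activation (0.00156), cell cycle (0.0187), oxidative phosphorylation (0.00484), inhibitory receptor (0.0293) and ribosomal protein (0.000482) genes fell as lists, with medians between -0.28 and -0.10. Of their members 10 Paneth and goblet cell genes and Rbp2 rose and 1 goblet cell gene fell, and 0 members of the other lists were called. When adjusted over the list alone 7 immunoglobulin constant, 5 MHC class II, 12 Paneth and goblet cell, 3 enterocyte, 1 IL-22 target, 1 stroma and 1 inhibitory receptor genes rose, and 3 cytotoxic, 3 T cell receptor activation, 2 inhibitory receptor and 2 Paneth and goblet cell genes fell. With an estimated correlation these lists had an adjusted p from 0.675 to 0.761. Without control replicates 1 and 2 and cystine replicates 1 and 2, in turn, 68, 4, 67 and 191 genes passed. Defa21, Defa30 and Rbp2 did not pass without control replicate 1, nor did these, Defa22 and Ang4 without control replicate 2.

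In CD4 T-like cells 6 genes rose and 0 fell of 5759, with 375 at an unadjusted p below 0.05 and 4 by DESeq2. These were Gal, the gene of the neuropeptide galanin (log2 fold change 5.25, SE 0.76, adjusted p = 0.0195; 2 and 0 UMIs in the controls, 60 and 29 in the cystine samples), the MHC class I gene H2-Q2 (3.59, adjusted p = 0.0195), the transcription factor gene Id3 (1.76) and the epithelial genes Defa24, AY761184 and Gm14851. Of 21 lists 8 passed. Naive and circulating T cell genes rose as a list (median 0.52, adjusted p = 2.01e-07), with 0 of 15 members called and 3 rises over the list alone. Of its members Tcf7 was at 1.15 (SE 0.19, adjusted p = 0.0525). Type 17 and type 22 genes (median -0.74, adjusted p = 4.19e-05), cytotoxic effectors (median -0.39, adjusted p = 0.000531) and tissue residency genes (median -0.28, adjusted p = 0.000994) fell as lists, with 0 members called and 4, 1 and 1 falls over the list alone. The 4 type 17 genes were Tmem176b (-0.95), Tmem176a (-0.98), Il17a (-2.06) and Ccr6 (-0.76), and Il22 rose when adjusted over the list alone, with 333 of its 339 UMIs in cystine replicate 2 from 1 barcode. Ribosomal protein (median 0.10, adjusted p = 0.000759), heat shock (0.28, 0.0142), epithelial IL-22 target (1.28, 0.0281) and Paneth and goblet cell (7.36, 2.48e-05) genes rose as lists, with Defa24 as the called member and 0, 0, 1 and 3 rises over the list alone. The IL-22 target list holds genes of the epithelium, another cell type. Its member Reg3b was at -1.71 without cystine replicate 2, while Socs3 and Reg3g stayed above 0 whichever sample was left out. The 8 lists had an adjusted p from 0.624 to 0.678 with an estimated correlation. Without control replicates 1 and 2 and cystine replicate 2, in turn, 52, 19 and 154 genes passed. Gal and H2-Q2 did not pass without cystine replicate 1.

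In monocyte-like cells, with 66 to 100 cells per sample, 18 genes rose and 46 fell of 3655. MHC class II genes fell, with Cd74 from 18700 ± 1188 to 6417 ± 177 CPM (log2 fold change -1.54, SE 0.11, adjusted p = 1.89e-05), H2-Aa at -1.45, H2-Ab1 at -1.45 and H2-Eb1 at -1.28. As a list they passed (adjusted p = 2.26e-14), with 5 of 8 members called and 6 over the list alone. The interferon-induced genes Gbp2 (-1.75) and Ifit2 (-2.78) fell, and the interferon list passed (adjusted p = 0.00326; 3 of 22 called, 4 over the list alone). Leading genes of dendritic clusters fell as well. Apol7c, which leads the type 2 dendritic-like cluster together with H2-Aa, H2-Ab1 and H2-Eb1, had 35 and 64 UMIs in the controls and 0 in the cystine samples, which allows up to 14.4 and 12.3 CPM. Klk1, a leading gene of the plasmacytoid dendritic-like cluster, and Adamdec1 also had 0 there. Chil3, a chitinase-like gene of monocytes and neutrophils, rose by 2.25 (SE 0.32, adjusted p = 0.00434), and Prtn3 and Lcn2, known from granulocytes, by 3.52 and 4.57. Transcripts known from T cells fell in the same cells, namely Cd8b1 (-4.72), Ctsw (-1.74), Ccl5 (-1.70), Nkg7 (-1.61), Gzma (-1.09) and the residency genes Ccr9 (-2.97), Jaml (-2.16) and Itgae (-1.81). Of these, Cd8b1 was also detected in 63.0% of the larger plasmacytoid dendritic-like cluster, and Ccr9 is among the markers of that class. The falls of Cd8b1 and Ccr9 therefore cannot be assigned to T cell RNA. The cytotoxic list (adjusted p = 1.08e-08; 4 of 9 called, 7 over the list alone), the residency list (3.30e-06; 3 of 14 called, 9 over the list alone) and ribosomal protein genes (0.00255; 0 of 23 called) fell, and glycolysis genes rose (0.00326; median 0.34, 0 of 11 called, 1 over the list alone). With an estimated correlation the 6 lists had an adjusted p from 0.382 to 0.534. Without control replicate 2 and cystine replicates 1 and 2, in turn, 111, 109 and 136 genes passed. Lcn2 did not pass without control replicate 2, Gzma without control replicate 1, or Klk1, Adamdec1, Ifit2 and Ccr9 without control replicate 1 and without control replicate 2. Ccr9 was also lost without cystine replicate 1 and Ifit2 without cystine replicate 2.

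In plasmacytoid dendritic-like cells Gzmb, a granzyme that these cells also make, fell from 347 ± 53.4 to 180 ± 19.3 CPM (log2 fold change -0.94, SE 0.14, adjusted p = 0.00486), and Rsrp1 fell by 0.61 (adjusted p = 0.0494). The 5 rises of the 7944 genes tested were epithelial secretory genes, among them Defa24 (1 UMI in each control, 202 and 653 in the cystine samples). In B-like cells 3 genes rose and 0 fell of 7008, again Defa24, AY761184 and Lyz1, with 348 genes at an unadjusted p below 0.05 and 5 by DESeq2. In plasmacytoid dendritic-like cells cytotoxic (adjusted p = 6.95e-07; 1 of 15 called, 3 over the list alone), cell cycle (0.00139; 0 of 13, 1) and residency genes (0.0159; 0 of 16, 1) fell as lists, and enterocyte (0.00139; 0 of 5, 3) and Paneth and goblet cell genes (0.000386; 3 of 4, 3) rose. In B-like cells interferon response genes rose as a list (median 0.36, adjusted p = 0.0124; 0 of 19, 1), as did enterocyte (0.0356; 0 of 5, 0) and Paneth and goblet cell genes (0.0315; 2 of 6, 5), while MHC class II (median -0.19, adjusted p = 3.03e-05; 0 of 12, 0) and cytotoxic genes (0.00135; 0 of 10, 1) fell. With an estimated correlation the adjusted p was 0.811 for the B-like lists and from 0.598 to 0.813 for the others. Without control replicates 1 and 2 and cystine replicates 1 and 2, in turn, 37, 26, 26 and 22 genes passed in plasmacytoid dendritic-like cells and 11, 9, 56 and 12 in B-like cells. Rsrp1 did not pass without control replicate 1 or cystine replicate 2, nor Lyz1 in B-like cells without control replicate 2.

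The lists closest to the amino acid itself passed in 0 of the 7 sets of cells at the preset correlation. Cysteine and glutathione metabolism had an adjusted p from 0.219 to 0.836 and medians from -0.10 to 0.10. For coenzyme A synthesis the adjusted p lay between 0.355 and 0.939, and for NRF2 targets, the genes of the oxidant response, between 0.244 and 0.841. Genes of the ATF4 response to amino acid shortage had an adjusted p from 0.291 to 0.764 (in CD8αβ T-like cells 1 of 15 members fell, Ddit4 at -0.975, named after its values were seen, and fry gave an adjusted p of 0.0461 for a fall), fatty acid oxidation genes from 0.242 to 0.942, and the X and Y linked genes from 0.307 to 0.942. The cystine importer subunit genes Slc7a11 and Slc3a2 had log2 fold changes of 1.52 (SE 1.03, 0 to 8 UMIs per sample) and -0.17 (SE 0.14) in all kept cells. Gclm, of glutathione synthesis, was at 0.11 (SE 0.17), Gpx1 at 0.58 (SE 0.11, adjusted p = 0.151), and the coenzyme A genes Pank1, Pank2 and Coasy at 0.53, 0.08 and 0.12. Averaged over classes with equal weight, Gpx1 was at 0.0015 and Pank1, measured in 5 classes, at -0.56. By the same average Gclm, Pank2 and Coasy were at 0.07, 0.18 and 0.17, Slc3a2 at -0.05 and Slc7a11, measured in 3 classes, at 1.78.

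**Figure D4:**
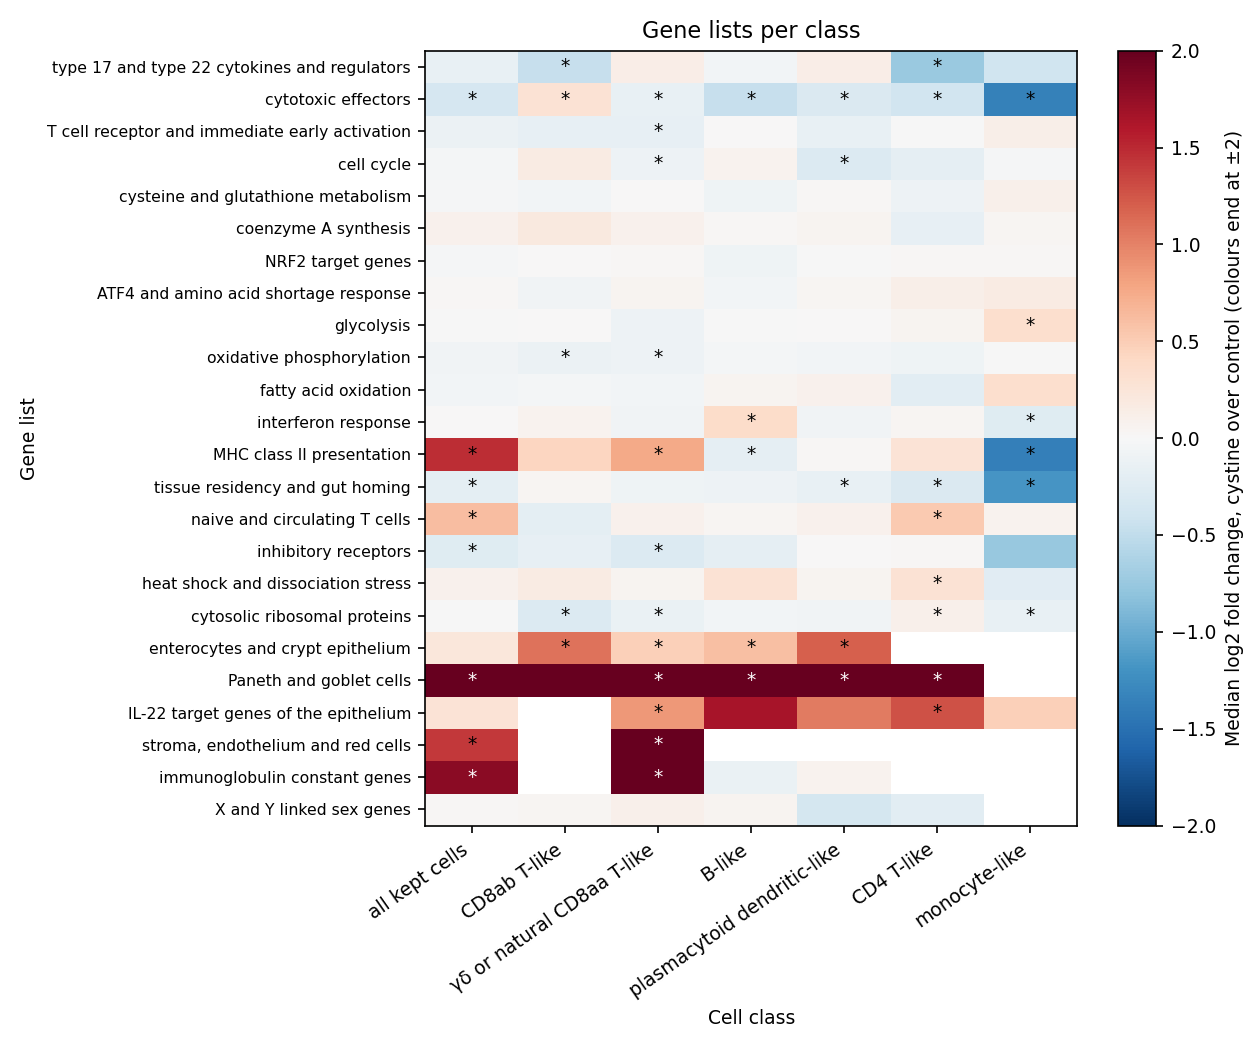
Median log2 fold change, cystine over control, of each gene list (vertical) in each set of cells (horizontal), with colours ending at -2 and 2; an asterisk marks an adjusted p below 0.05 by camera at the preset correlation. Paneth and goblet cell genes lie above 0 wherever at least 3 were measured, and the cysteine and glutathione list stays between -0.10 and 0.10.

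Paneth cell transcripts, counted as the UMIs of 11 genes, were found in 0.309% (95% interval 0.226% to 0.413%) and 0.341% (0.250% to 0.455%) of control cells. In cystine replicates 1 and 2 they were in 29.8% (29.1% to 30.5%) and 8.66% (8.20% to 9.13%) of cells. The tested classes lay close together within each cystine sample, from 28.1% to 33.7% in replicate 1 and from 7.25% to 10.8% in replicate 2. Plasmacytoid dendritic-like and CD4 T-like cells, neither of which is a source of defensins, had 28.1% and 33.7% in cystine replicate 1 at median depths of 2496 and 1406 UMIs.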

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

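The results in this part come from a test planned before the data were examined, the interaction of diet and cell class, with the sample as a block. The diet effect differed between CD8αβ T-like and CD4 T-like cells for 24 of 6672 genes (edgeR quasi-likelihood, Benjamini-Hochberg), 5 with a higher and 19 with a lower effect in CD8αβ T-like cells, and 534 genes had an unadjusted p below 0.05. The named genes are given with the difference of the log2 fold changes, CD8αβ T-like minus CD4 T-like.

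The activation marker gene Ly6a differed by 2.07 (SE 0.28, adjusted p = 0.00088), from 1.93 in CD8αβ T-like and -0.10 in CD4 T-like cells. The tissue homing receptor gene Cxcr6 differed by 1.78 (adjusted p = 0.0197; 0.72 and -1.10). The chemokine genes Ccl4 and Ccl5 differed by 1.88 (1.19 and -0.68) and 0.52 (0.47 and -0.04), each at an adjusted p of 0.0471. Izumo1r, also called folate receptor 4 and known from regulatory T cells, differed by -3.68 (adjusted p = 0.00023; -1.93 and 1.76), Nsg2 by -3.37 (adjusted p = 0.00088; -2.54 and 0.90), Gstp3 by -3.15 (adjusted p = 0.0266; -2.31 and 0.84) and Tmem176b by -2.87 (adjusted p = 0.0441; -3.87 and -0.95).

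Ly6a, Cxcr6, Izumo1r and Nsg2 kept their call under each alternative run with all 4 samples, and their sign in each fit without 1 sample. None of the alternatives run for the interaction changed how the classes were defined. Izumo1r and Tmem176b are leading genes of the CD4 T-like cluster and Nsg2 of a γδ or natural CD8αα T-like cluster. Whether these differences come from which cells each class holds was not tested. Ccl4 was not called without control replicate 2 (1.03), Ccl5 without control replicate 2 or cystine replicate 1, Gstp3 without control replicate 1 (-2.28), and Tmem176b without either control or without cystine replicate 2. In these fits the number of genes lay between 30 and 120.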

How the results depend on the processing

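The fits without the barcode with the most Il22 UMIs, without epithelial secretory genes, and with other clustering genes were chosen after the results were seen; the other alternatives were planned. With 2 samples per diet, a fit that leaves 1 out assumes that the lone sample varies like the other group. Over all results and alternatives 3329 values kept direction and side of the threshold, 271 passed in addition, 194 no longer passed, 140 moved and 51 turned. Depth limits rare classes, with 66 monocyte-like cells in the smallest sample, and rare transcripts, with 0 cells with an Il22 UMI among CD8αβ T-like cells, which allows 0.199% to 1.06% of cells with such a UMI and says nothing of cells that express Il22 without one.

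Numbers of changed genes moved as follows, with the cause not tested. The DESeq2 Wald test gave 367 in all kept cells, 33 in CD8αβ T-like, 50 in γδ or natural, 37 in monocyte-like and 5 in B-like cells, and DESeq2 size factors 1 in B-like cells. Without a low count filter there were 11 in all kept cells, 0 in CD8αβ T-like, 292 in γδ or natural, 52 in B-like, 37 in plasmacytoid dendritic-like, 68 in CD4 T-like and 169 in monocyte-like cells, 85 for the interaction, and 1, 8 and 12 lists in B-like, CD8αβ T-like and monocyte-like cells. With the replicate number as a block these were 405, 220, 222, 50, 33, 96 and 20 genes in the same order of classes, and 8 lists in CD8αβ T-like cells. The strict cell filter gave 12, 45, 13, 8, 4 and 3 in all kept, CD8αβ T-like, γδ or natural, B-like, plasmacytoid dendritic-like and CD4 T-like cells, and 1 and 5 lists in B-like and CD4 T-like cells. With doublets kept there were 12 in all kept and 19 in plasmacytoid dendritic-like cells and 50 for the interaction. Without immunoglobulin and T cell receptor genes there were 62 in all kept cells. Without secretory genes, themselves among the called genes, there were 9 in all kept, 5 in γδ or natural, 0 in B-like, 1 in plasmacytoid dendritic-like and 2 in CD4 T-like cells, and 3 lists each in B-like and plasmacytoid dendritic-like cells. An estimated correlation gave 0 lists in all 7 sets of cells, and fry 2 in CD8αβ T-like cells (T cell receptor activation and ATF4 genes, not among those that camera called), 1 in monocyte-like cells (residency genes) and 0 in the other 5 sets. T cells as the denominator gave 2 classes with a changed share (CD8αβ T-like 2.23, γδ or natural -0.15), TMM 1 (2.37) and omission of B-like and plasma cell-like cells 1 (2.17). With T cells as the denominator the shares add up to the whole, so these 2 changes are not separate results.

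Il22 passed in CD4 T-like cells without a low count filter (log2 fold change 3.84), with the block (3.12), without control replicate 1 (3.82) and without cystine replicate 1 (4.80), and in all kept cells without cystine replicate 1 (4.42); without its top barcode it was -1.14 there and -1.34 in all kept cells. Other values, not called before, turned in sign. In the UMI-defined CD8αβ class they were Coasy -0.16, Epcam -0.12, Gclm -0.0121, Gpx1 0.0858, Gzma -0.50, Mki67 -0.66, Pank2 -0.25 and Reg3g -1.61. With doublets kept they were Apoa1 in B-like cells -0.0248, Hba-a1 and Hbb-bs in γδ or natural cells -1.76 and -1.12, Hba-a2 and Hbb-bs in all kept cells -2.25 and -1.39, and Mki67 in CD8αβ T-like cells -0.29. The block gave Reg3g -0.17 in all kept cells and a mast-like share of -0.12, resolution 0.5 a monocyte-like share of 0.19, and the strict filter H2-Ab1 0.00537 in B-like and Pank1 -0.59 in CD8αβ T-like cells and shares of -0.0191 for CD4 T-like and -0.11 for mast-like cells.

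Leaving out 1 sample gave 0 to 895 changed genes in all kept cells, 95 to 223 in CD8αβ T-like, 4 to 191 in γδ or natural, 9 to 56 in B-like, 22 to 37 in plasmacytoid dendritic-like, 5 to 154 in CD4 T-like and 88 to 136 in monocyte-like cells, and 30 to 120 for the interaction. Lists numbered 4 to 8 in CD8αβ T-like, 5 to 11 in γδ or natural, 2 to 7 in B-like, 4 to 8 in plasmacytoid dendritic-like and 5 to 7 in CD4 T-like cells. Log2 fold changes ranged in all kept cells from -1.87 to 4.42 for Il22, -0.0234 to 0.27 for Coasy, -0.12 to 0.28 for Gclm, -0.75 to 0.0390 for Mki67, -0.0874 to 0.24 for Pank2 and -1.5 to 1.0 for Reg3g. In CD8αβ T-like cells they ranged from -0.14 to 0.0209 for Cd8b1, -0.0235 to 0.49 for Gclm, 0.0399 to 0.62 for Gzma, -0.91 to 0.26 for Gzmb, -0.0787 to 6.06 for Mki67, -0.44 to 4.25 for Pank1 and -0.19 to 3.74 for Reg3g. In γδ or natural cells they ranged from -0.52 to 7.73 for Hba-a1, -0.0267 to 0.29 for Pecam1, -0.66 to 3.53 for Reg3b and -0.66 to 3.27 for Reg3g. In B-like cells Apoa1 ranged from -0.61 to 2.58, Epcam from -0.0587 to 2.83 and Rbp2 from -0.17 to 3.13, and in CD4 T-like cells Il22 from -1.35 to 4.80 and Reg3b from -1.71 to 7.47. Zg16 in plasmacytoid dendritic-like cells ranged from -1.03 to 0.0444, the CD4 T-like share from -0.11 to 0.51 and the mast-like share from -1.20 to 0.79.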

Other observations

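The tests on depth and on Paneth cell transcripts were planned before their results were seen; those on carried-over cells and on the Il22 barcode were chosen afterwards.

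The γδ or natural CD8αα T-like class held clusters with distinct programmes. A cluster led by Il2rb, Klra5 and Spp1 held 18.5% ± 1.77 of the class on the control and 25.5% ± 2.41 on the cystine diet (n = 2 each), and one led by Gzmk, Scin, Trdv5 and Ccl5 17.5% ± 5.78 and 6.78% ± 0.894. Clusters led by Tcf7 and Thy1 (8.88% ± 0.556 and 9.14% ± 0.693) and by Xcl1 and Batf3 (6.06% ± 0.372 and 6.33% ± 0.612) differed less between diets than between samples. A cluster led by immediate early genes such as Nr4a1 and Egr1 held 2.20% ± 0.0856 and 1.61% ± 0.0311, and proliferating cells with Top2a and Mki67 held 1.24% ± 0.335 and 1.05% ± 0.0703. These shares were not tested.

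Of the 6 unnamed clusters, 4 are described here. A cluster led by the natural killer genes Ncr1 and Klra7, with Cd3e in 67.4% of its 500 cells, held 0.971% ± 0.376 and 0.736% ± 0.0707 of kept cells. A cluster led by Ifit1, Isg15 and Cxcl10, genes induced by interferon, with Cd3e in 97.6% of its cells, held 0.373% ± 0.197 and 0.335% ± 0.0577. A cluster with B cell genes such as Pax5 and Ebf1 and Cd3e in 67.5% of cells held 94 and 0 cells in the controls and 352 and 77 in the cystine samples. A cluster with the enterocyte genes Fabp1, Apoa1 and Rbp2 held 0.417% ± 0.159 and 0.620% ± 0.443.

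Paneth cell transcripts were higher in every tested class of cystine replicate 1, and in all but monocyte-like cells of cystine replicate 2, than in the controls. More crypt base material was predicted to raise Olfm4, a stem cell gene of the crypt base, by at least 1 on the log2 scale. The change of Olfm4 was -0.44 (SE 0.74), below that bound by more than the SE. The bound was assumed, and 1 gene in 2 samples per diet cannot exclude more crypt base material. Free RNA in the droplets may contribute. Paneth UMIs in CPM differed 2.38-fold between the highest and the lowest class in cystine replicate 1 and 9.33-fold in cystine replicate 2, which leaves it open. The lowest class of cystine replicate 2 was monocyte-like, with only 28 Paneth UMIs and 114 CPM. The other tested classes of that sample lay between 477 and 1068 CPM. Droplets that also hold a Paneth cell stay open too, since the 1% of cells with the most Paneth UMIs held 18.1% of them in cystine replicate 1 and 57.8% in cystine replicate 2. Paneth cells lack CD45 and should not pass the sort, and a change in Paneth cells with the diet was not tested.

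The CD8αβ T-like share was higher in both cystine samples, without passing the test over all kept cells. Depth per cell does not account for it: after thinning every cell to 1000 UMIs and choosing the cells by their UMIs, the log2 ratio of the mean shares was 1.27. Cells carried over from lymphoid follicles or blood might also raise it, and B-like cells were more frequent in both cystine samples. The naive and circulating list had a median of -0.20 in CD8αβ T-like cells, but with an SD of 1.01 over its members this leaves carry-over open, as it does an effect of the diet on these cells.

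The Il22 UMIs of cystine replicate 2 came almost all from 1 barcode. A rise of Il22 in many CD4 T-like cells, large enough for this excess, would raise the share of cells with an Il22 UMI at least 5-fold, and after thinning the upper 95% limit of that share in cystine replicate 2 was 1.31 times the control mean. A fall of Il22 in many cells on the cystine diet stays open, as the share was 4.07% ± 0.0975 and 1.24% ± 0.127 (exact permutation p = 0.333, the smallest these samples allow). These shares rest on 12 and 7 cells in the controls and 3 and 4 in the cystine samples. A doublet also stays open: among all barcodes of the sample that passed the cell filter, the doublet score lay at a mean percentile of 59.5 (SD 3.52 over 5 seeds), but the barcode had more UMIs than 93.0% of its class and UMIs of Gzma and Ccl5 with few of Cd3, and the score does not see doublets of like cells. Whether cells with much Il22 RNA depend on the diet cannot be read from 1 barcode.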
